A study of Mus musculus with 8 samples.

How the data were processed

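RNA of 4 wild type and 4 Sel1L knockout samples of mouse pancreas, of the C57BL/6J background, was profiled on 8 arrays. Per the labels' protocols, exon 6 of Sel1l was floxed in both groups, the knockout group carried an actin-promoter driven estrogen receptor-Cre fusion that the littermate controls lacked, and mice aged 8 to 20 weeks were injected daily with tamoxifen (5 mg/ml, 5 μl per g body weight) for 3 days. Pancreas was perfused with an RNA stabiliser before excision, and 100 ng of RNA entered whole-transcript cDNA synthesis, per the labels' protocols. Because controls lacked Cre, the effect of deleting Sel1l and that of active Cre cannot be told apart by this design. The labels number the samples 1 to 4 in each group but do not say that each number is a separate animal, so p-values then measure only the spread between these samples, which may be technical. The sample descriptions carry letter codes that differ between the groups; if these are array positions, which the labels do not say, position and genotype were confounded.

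The deposited values were made with RMA (robust multi-array average), per the submitters' processing notes; its version, the chip definition and the set of arrays normalized together are not given in the sources used here. The deposited values are on a log2 scale as far as RMA and their range imply, since no header names the log base. The lowest value was 0.965 and the highest 14.4, and the array medians lay between 4.94 and 5.05. The table held 35556 features. GEO's platform annotation gave 1 gene symbol for 21218 of them and several for 1881, and 12457 had no gene listed. Symbols were checked through Entrez identifiers against the RefSeq gene table of the GRCm38.p6 assembly, which held 21185 of the features' identifiers and changed 0 symbols; no coordinates were used because the series names no build. Features with several symbols or none were left out of the gene-level test. Of several features of a gene the one with the highest mean over the 8 arrays was kept (2398 left out), which gave 18820 genes. No filter on dim genes was applied.

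Genotype was fitted with limma 3.58.1 (lmFit and eBayes with default settings, 6 residual degrees of freedom) in R 4.3.3, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Differences are log2 knockout minus wild type, and errors are the moderated standard errors. Sel1l was also tested by an exact two-sided permutation test. Gene lists were tested with camera (inter-gene correlation preset at 0.01), Benjamini-Hochberg adjusted over the 39 lists with at least 5 measured genes. Camera with a correlation estimated per list and fry, which tests whether a list's genes move on balance one way and does not compare the list with other genes, were run as alternatives. The 24 pathway lists and 16 marker lists are each reported with their members called over all genes and when adjusted over the list alone. Some members are shared between lists: Slc38a5 (acinar function; alpha, delta and PP cells), Me1 (NRF2 targets; fatty acid synthesis), Ero1b (ER chaperones; beta cells), Atf4 (PERK-ATF4-CHOP targets; UPR sensors), Xbp1 and Bhlha15 (UPR sensors; acinar transcription factors), Sesn2 and Bbc3 (PERK-ATF4-CHOP targets; p53 targets), Slc7a11 (PERK-ATF4-CHOP targets; NRF2 targets), Ttr (alpha, delta and PP cells; gut and liver), and Acta2, Tagln and Des (stellate cells; muscle).

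The test, the lists, the naming rule and the other settings listed below were set before the data were examined. Named genes were Sel1l, the 12 largest rises and the 12 largest falls among called genes with non-overlapping groups (predicted genes, receptor families and small RNAs left out), a fixed set of ERAD and stress genes, and up to 4 members of each list with the smallest p. In lists that were not called this was narrowed to at most 2 after the data had been seen. Genes named outside this rule are said to be. Lists of sex-linked and C57BL/6 substrain genes were checked outside the set tests: Nnt, Wdfy1 and Entpd4 did not pass the threshold between groups (adjusted p = 0.973, 0.187 and 0.772).

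These settings were quantile normalization of the deposited values, centring each array on its median, only genes above the median level, every feature tested by itself, the mean of all features of a gene, trend and robust variance, array weights, the Xist level as a covariate, the replicate number as a block, and leaving out each array in turn. Cyclic loess between arrays was added after seeing the data. The computation was tested on simulated data in which 200 of 18820 genes were changed between 4 and 4 arrays. There limma recovered 39% of those changed by 0.5 and 89% of those changed by 1 on the log2 scale, with 7 false calls among 135. The simulated genes varied independently and far fewer were changed than were called in the real data, so these rates do not carry over to it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.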

Results

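Gene expression was measured in the pancreas of mice in which Sel1L, the adaptor of the Hrd1 ubiquitin ligase in endoplasmic reticulum (ER) associated degradation (ERAD), could be deleted by tamoxifen. The 8 whole-transcript arrays comprised 4 of wild type and 4 of Sel1L knockout pancreas. Per the labels' protocols, both groups carried the floxed Sel1l gene. Per the same protocols, the knockout group also carried a tamoxifen-activated Cre recombinase fused to the estrogen receptor and driven by an actin promoter. The series has 1 comparison, which asks how loss of Sel1L alters gene expression in this tissue. An actin promoter is not limited to pancreas. Effects of losing Sel1L in other tissues therefore cannot be told apart from those of losing it in pancreas. The number of arrays limits the precision of each value.

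The median level per array lay between 4.94 and 5.05 on the log2 scale. Pearson correlations were taken across the 18820 genes, which are not independent replicates. They ranged from 0.979 to 0.992 within the wild type group and from 0.992 to 0.995 within the knockout group. Between groups they ranged from 0.968 to 0.983. The first principal component held 53.7% of the variance and separated the groups. The next held 20.8%, and wild type replicate 2 lay apart on it, at -35.7. In that array the mean of the macrophage markers was 5.68, against 7.41 to 8.12 in the other wild type arrays, that of the stellate cell and fibroblast markers 6.52, against 7.71 to 8.09, and that of the Reg family and acinar injury list 7.39, against 8.84 to 9.40. On all 8 arrays Xist lay between 10.7 and 11.25, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 1.96 and 2.83. High Xist with low Y-linked genes on every array is the pattern of female mice.

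**Figure D1:**
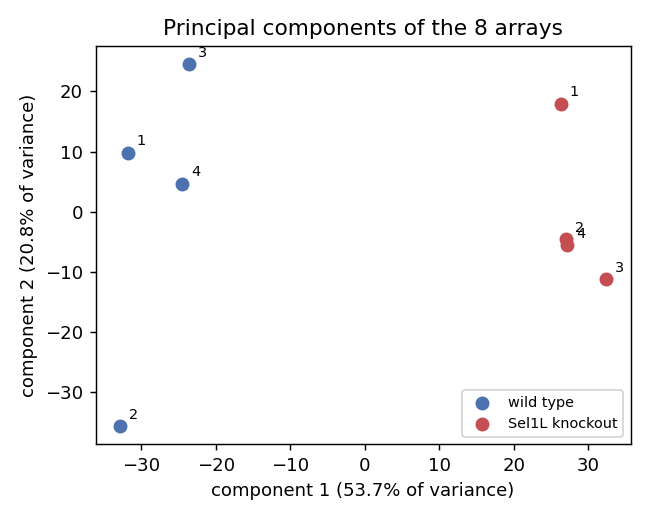
Scores of the 8 arrays on the first 2 principal components, with each component's share of the variance on its axis; points are arrays, colours are groups and numbers are replicates. The groups separate on the horizontal axis, which holds 53.7% of the variance, and wild type replicate 2 lies lowest on the vertical axis.

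Sel1l itself was lower in the knockout arrays, at 11.62 ± 0.114 (SD, n = 4) against 12.38 ± 0.0105 (SD, n = 4) on the log2 scale. The difference was -0.76 (SE 0.0788, limma adjusted p = 0.000196), a 1.69-fold fall, and all 4 knockout values lay below all 4 wild type values (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). Exon 6 was the floxed part, and a whole-transcript feature also holds probes outside it, so the residual signal does not measure the share of cells that lost the exon. Esr1, which encodes the estrogen receptor and was looked at after its value was seen, rose by 2.15 (SE 0.183, adjusted p = 7.53e-05).

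Of 18820 genes tested, 5406 changed (28.7%), of which 3027 were higher and 2379 lower in the knockout arrays. A change of at least 2-fold was found for 434 genes, with 285 higher and 149 lower. The groups did not overlap for 32.2% of the genes tested, where chance gives 2.86%. Higher genes made up 56.0% of the calls on the deposited values, 42.9% after quantile normalization, 31.8% after centring each array on its median and 48.1% after cyclic loess, so the balance of directions was not fixed by these data. Without Sel1L knockout replicate 3, 1517 genes were lower. With the Xist level as a covariate 181 genes were called and Sel1l missed the threshold (adjusted p = 0.0587); Xist itself was higher in the knockout arrays by 0.34 (adjusted p = 0.0165), so this covariate overlaps with genotype.

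Among the 12 largest rises, Fetub, which encodes a plasma protease inhibitor of the fetuin family, rose by 5.48 on the log2 scale (SE 0.431, 44.5-fold), from 6.01 ± 1.07 to 11.48 ± 0.127 (SD, n = 4 each). Cps1, the mitochondrial enzyme that starts the urea cycle, rose by 5.33 (SE 0.24), and Ahsg, another fetuin, by 4.38 (SE 0.311). Agr2, a protein disulfide isomerase of secretory cells, rose by 4.33 with a wider error (SE 0.653). Trib3, a pseudokinase induced by ATF4, rose by 3.72 (SE 0.174, 13.1-fold). The other largest rises, in decreasing order, were in Ndnf (4.35), B4galnt2 (4.02), Kirrel3 (3.74), Acot2 (3.56), Paqr3 (3.33), Serpina6 (3.33) and Steap1 (3.20), with Ndnf lying between Ahsg and Agr2 in size. Among the falls, Gal, the gene of the neuropeptide galanin, changed by -4.26 (SE 0.398), a 19.1-fold fall from 11.85 ± 0.364 to 7.59 ± 0.926 (SD, n = 4 each). Smim24 changed by -4.19 (SE 0.247), Hamp2, a hepcidin gene, by -4.08 (SE 0.208), and Vtn, the gene of vitronectin, by -3.37 (SE 0.206). The next falls were in Pgf (-3.23), Fat3 (-2.74), Susd2 (-2.67), Lcat (-2.56), Fxyd1 (-2.56), Muc1 (-2.39), Fxyd6 (-2.35) and Cdhr2 (-2.19). All of these genes had adjusted p-values of 0.00265 or less. A call and non-overlapping groups were conditions for being named here. The wild type levels of Cps1 (4.30), Ahsg (3.59), Ndnf (3.96), B4galnt2 (4.30), Kirrel3 (4.81) and Steap1 (4.07) and the knockout level of Cdhr2 (3.66) lay below every array's median, so the sizes of these differences are rough.

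**Figure D2:**
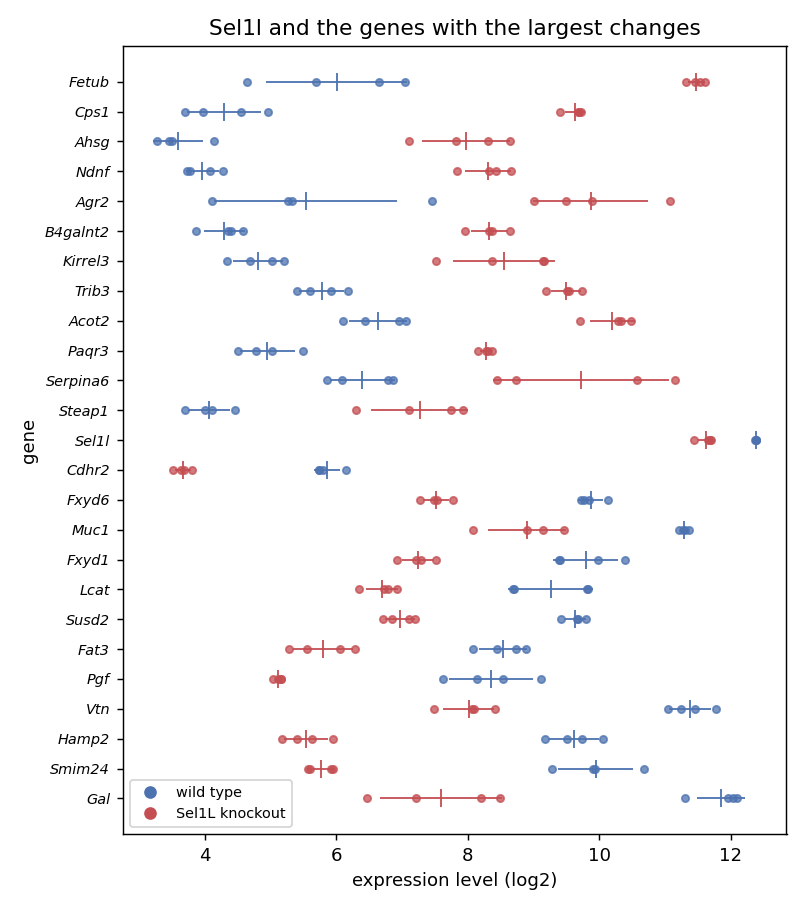
Expression level (log2, horizontal axis) of Sel1l, and of the 12 largest rises and the 12 largest falls among called genes with non-overlapping groups. Points are arrays, vertical ticks are group means and bars are 1 SD over 4 arrays. Fetub moved from a mean of 6.01 to 11.48 and Gal from 11.85 to 7.59. The colours do not overlap in any gene shown, which for all but Sel1l was a condition for being shown.

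More genes of protein folding and processing in the ER rose than fell. Of 27 ER chaperones and folding enzymes measured, 18 rose and 1 fell (20 and 3 when adjusted over the list alone), and the list was higher than other genes (camera adjusted p = 2.72e-08, but adjusted p = 0.509 with an estimated correlation). The oxidase gene Ero1a rose by 1.30 (SE 0.117), Hsp90b1, the ER member of the Hsp90 family, by 1.21 (SE 0.114), Pdia3 by 1.03 (SE 0.102), and Hspa5, the gene of the chaperone BiP, by 0.76 (SE 0.0904). Dnajb9 rose by 0.64 (SE 0.135). Ero1b, also on the beta cell list, was the 1 member that fell. The N-glycosylation genes that changed moved one way, with 22 of 32 higher and 0 lower (24 and 0 adjusted over the list alone; camera adjusted p = 1.25e-10, adjusted p = 0.509 with an estimated correlation). The mannosyltransferase gene Alg12 rose by 1.42 (SE 0.0801), Dpm2 by 1.03 (SE 0.0877) and Stt3a, a catalytic subunit of the oligosaccharyltransferase, by 0.77 (SE 0.0922).

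In the list of ER translocation and signal peptidase genes, 13 of 22 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 6.66e-05, adjusted p = 0.509 with an estimated correlation). Sec11a, a signal peptidase subunit, rose by 1.23 (SE 0.0841) and Sec61g, a subunit of the translocation channel, by 0.54 (SE 0.0943), while Sec62 fell by 0.62 (SE 0.0918). For ER-Golgi transport, 17 of 34 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 3.31e-05, adjusted p = 0.509 with an estimated correlation). Tmed9 rose by 1.11 (SE 0.0942), Sar1b, a GTPase of vesicle budding, by 0.65 (SE 0.0784) and Kdelr2, a receptor that returns ER proteins, by 0.66 (SE 0.0933).

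The ERAD machinery, in which Sel1L itself works, rose in part: 10 of 26 members were higher and 2 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.00495, adjusted p = 0.534 with an estimated correlation). Syvn1, which encodes the Hrd1 ligase, rose by 0.95 (SE 0.13). The derlin genes rose as well, Derl3 by 1.03 (SE 0.0877), Derl1 by 0.89 (SE 0.0742) and Derl2 by 0.85 (SE 0.109). Differences for Herpud1 (0.22, adjusted p = 0.0941), Os9 (0.22, adjusted p = 0.0571) and Edem1 (-0.23, adjusted p = 0.0748) did not pass the threshold over all genes; with trend and robust variance they did (0.0313, 0.0161 and 0.0235). The list call was lost after cyclic loess (adjusted p = 0.0821, list median 0.11 against 0.22) and among genes above the median level (adjusted p = 0.403, list median 0.22), where all genes compared had a median of 0.13 against -0.04.

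Stress response genes did not move as a block. Among PERK-ATF4-CHOP targets, 12 of 33 rose and 7 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0455, adjusted p = 0.711 with an estimated correlation). Besides Trib3, Stc2 rose by 1.56 (SE 0.128), Cebpg by 0.94 (SE 0.0856) and Atf4 by 0.52 (SE 0.101), while Cbs, an enzyme of cysteine synthesis, fell by 0.81 (SE 0.0767). The list call was lost without wild type replicate 1 (adjusted p = 0.128), wild type replicate 3 (0.074), Sel1L knockout replicate 3 (0.0682) or Sel1L knockout replicate 4 (0.0802), with list medians of 0.16, 0.17, 0.15 and 0.17 against 0.19. It was also lost after quantile normalization (0.0734), after cyclic loess (0.163), with a list median of 0.07 after either, and among genes above the median level (0.847), with a list median of 0.19. With the replicate number as a block it was lost as well (camera adjusted p = 0.0563, list median 0.19). Of 15 UPR (unfolded protein response) sensors and transcription factors, 6 rose and 2 fell (7 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.075). It was called without wild type replicate 2 (0.0336) or Sel1L knockout replicate 1 (0.0455) and with fry (0.0143). Ern1, the gene of the sensor IRE1 alpha, rose by 0.80 (SE 0.0888). Xbp1 fell by 0.50 (SE 0.135) and Bhlha15, also an acinar transcription factor, by 0.76 (SE 0.084). These gene-level values do not read the splicing of Xbp1 RNA, so they do not tell the activity of IRE1 alpha. Cytosolic tRNA synthetases went both ways, with 8 of 17 higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.156, fry adjusted p = 0.0243), and Eprs rose by 0.89 (SE 0.0979). Ddit3 had no feature of its own and was not analysed here.

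More p53 targets and cell death genes rose than fell: 11 of 24 were higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.000279, adjusted p = 0.509 with an estimated correlation). Eda2r rose by 2.70 (SE 0.164), Phlda3 by 2.49 (SE 0.165), Zmat3 by 2.16 (SE 0.142) and Trp53inp1 by 1.46 (SE 0.0869), each with non-overlapping groups. Controls lacked Cre, so genotype and Cre activity cannot be told apart for this list. In the cell cycle list 3 of 31 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.915; median -0.07, mean 0.01), including Ccnd1, the gene of cyclin D1, which rose by 1.47 (SE 0.146).

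More genes of digestive enzymes and other functions of the acinar cell fell than rose. Of 28 digestive enzymes and zymogen granule proteins, 17 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 1.23e-06, adjusted p = 0.509 with an estimated correlation), with a median of -0.30. Cuzd1 fell by 1.02 (SE 0.113), Dmbt1 by 0.97 (SE 0.109) and Pla2g1b, a secreted phospholipase, by 0.80 (SE 0.0731), while the amylase gene Amy1 rose by 1.12 (SE 0.108). Enzyme families hold near-identical copies, whose probes can share signal. Several members also lay near the top of the arrays' range, such as Ctrb1 at 14.08 in wild type, where array maxima were 14.29 to 14.37. Whether signals this high still follow the RNA amount was not tested, so the sizes of such falls are rough. The list call was lost after quantile normalization (adjusted p = 0.0581), where its median was -0.08. Other acinar function genes showed 11 of 23 lower and 2 higher (12 and 4 adjusted over the list alone; camera adjusted p = 0.00163, adjusted p = 0.509 with an estimated correlation). The amino acid transporter gene Slc38a5 fell by 1.71 (SE 0.0795), and the creatine synthesis genes Gatm and Gamt by 1.12 (SE 0.0961) and 1.06 (SE 0.0807). Of 9 acinar transcription factors 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.187), the latter being Prox1 (1.00, SE 0.179). The list was called lower after cyclic loess (adjusted p = 0.036), among genes above the median level (0.0346) and with fry (0.0243).

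The Reg family and acinar injury list had 4 of 18 members lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.123), with Clu, the gene of clusterin, at -0.78 (SE 0.107). It was called lower without wild type replicate 2 (adjusted p = 0.00149), which held the lowest wild type mean as given above, or Sel1L knockout replicate 1 (0.0451), and among genes above the median level (0.0225). Inflammation and NF-kB targets had 1 of 27 higher, Birc3, and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.156). That list was called lower without wild type replicate 2 (0.00367), in which its mean was 4.65 against 5.22 to 5.73 in the other wild type arrays, or Sel1L knockout replicate 1 (0.0363).

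More proteasome subunits rose than fell: 10 of 31 were higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 0.000279, adjusted p = 0.509 with an estimated correlation), with Psmb4 at 0.60 (SE 0.101) and Psmd6 at -0.55 (SE 0.0736). The call was lost after cyclic loess (adjusted p = 0.0805, list median 0.13 against 0.26) and among genes above the median level (0.0984, list median 0.26). Ribosomal protein genes had 16 of 32 higher and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p = 7.09e-07, adjusted p = 0.509 with an estimated correlation), with Rps24 at 0.49 (SE 0.0699). Of 23 interferon-stimulated genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0175, adjusted p = 0.711 with an estimated correlation), among them Rtp4 (0.76, SE 0.189). The list mean in wild type replicate 2 was 4.90, against 5.26 to 5.61 in the other wild type arrays. This call was lost without that array (adjusted p = 0.0736) or Sel1L knockout replicate 1 (0.0617), with a median of 0.21 in either against 0.32, among genes above the median level (0.474, median 0.49) and with fry (0.213), and its direction turned with the Xist covariate (median -0.19).

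The remaining pathway lists were not called by camera; with fry those of NRF2 targets (adjusted p = 0.0194), autophagy and lysosome (0.0256) and fatty acid synthesis (0.0243) were. NRF2 targets, genes of the antioxidant response, had 8 of 25 higher and 3 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.143), with the transporter gene Abcc4 up by 2.35 (SE 0.191) and Osgin1 up by 0.85 (SE 0.0983). Of 27 autophagy and lysosome genes 6 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.506), with Sqstm1 at 0.55 (SE 0.0712) and Ulk1 at -0.72 (SE 0.0977). Cytosolic heat shock proteins had 2 of 16 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.616), with a median of -0.03 against a mean of 0.07. Both that rose, Hspe1 (0.69, SE 0.0761) and Hspd1 (0.57, SE 0.0826), encode mitochondrial chaperonins. Cholesterol synthesis had 6 of 20 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.229), with Lss at 0.93 (SE 0.14). Fatty acid synthesis had 3 of 20 higher and 6 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.229), with Scd1 at 0.87 (SE 0.0858) and Me1, also an NRF2 target, at 0.84 (SE 0.124). Oxidative phosphorylation had 3 of 33 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.653), with Ndufa1 at -0.66 (SE 0.103). The lists of fatty acid synthesis and oxidative phosphorylation were called lower after cyclic loess (adjusted p = 0.0345 and 0.0382) and among genes above the median level (0.00138 and 0.0415).

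Markers of other pancreatic cell types moved in both directions. Duct cell markers had 5 of 14 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0288, adjusted p = 0.509 with an estimated correlation). The keratin gene Krt18 rose by 0.86 (SE 0.0771) and the adhesion gene Epcam by 0.67 (SE 0.0852), whereas Muc1 was among the largest falls. Endothelial markers had 7 of 14 higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.509 with an estimated correlation), with Esam at 0.54 (SE 0.0985) and Tie1 at 0.49 (SE 0.0936). Both calls were lost after quantile normalization (adjusted p = 0.0741 for duct and 0.0615 for endothelial cells), after cyclic loess (0.0887 and 0.0805), among genes above the median level (0.474 and 0.0984) and with the Xist covariate (0.463 and 0.0933). The list medians were 0.27 for duct and 0.34 for endothelial cells on the deposited values, 0.20 and 0.18 after quantile normalization, 0.22 and 0.20 after cyclic loess, 0.27 and 0.38 among genes above the median level and 0.19 and 0.27 with the Xist covariate.

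Neutrophil markers had 3 of 13 lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.00764, adjusted p = 0.509 with an estimated correlation), and T cell markers also 3 of 13 lower and 0 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.0288, adjusted p = 0.509 with an estimated correlation). Camp, an antimicrobial peptide gene of neutrophils, fell by 0.44 (SE 0.104) from a level of 4.28, and Bcl11b, a T cell transcription factor, fell by 0.44 (SE 0.107) from 4.77. These are dim genes, and 1192 olfactory, vomeronasal and taste receptor genes, which pancreas is not known to express, had a median difference of -0.18 in the same direction. The calls were lost after quantile normalization (adjusted p = 0.0725 for neutrophils and 0.116 for T cells) and cyclic loess (0.0805 and 0.163), with list medians of -0.26 and -0.22 for neutrophils against -0.34, and of -0.21 and -0.17 for T cells against -0.27. The T cell call was also lost without wild type replicate 1 (0.0693, median -0.20) and with the Xist covariate (0.224, median -0.16).

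The remaining marker lists were not called by camera; with fry that of alpha, delta and PP cells was (adjusted p = 0.0334). Beta cell markers had 4 of 11 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.285), with the transcription factor gene Pdx1 at -0.75 (SE 0.123). The median of that list was 0.00 and its mean -0.13. Markers of alpha, delta and PP cells had 2 of 8 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.653, directed down although the median was 0.01). Slc38a5 is on this list as well as the acinar one, and Hhex, a delta cell factor, rose by 1.05 (SE 0.207). Neuroendocrine genes had 1 of 12 higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.653), with Cpe at -0.82 (SE 0.2). For stellate cells and fibroblasts 0 of 22 markers changed by limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05; camera adjusted p = 0.653), and the list was called lower without wild type replicate 2 (adjusted p = 0.00363), the array with the lowest mean of these and of the macrophage markers. Macrophage markers had 1 of 18 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.653), namely Ms4a7 (1.14, SE 0.267). B cell markers had 2 of 15 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.763), with Ebf1 at 0.75 (SE 0.124); the list median was -0.10 and the mean 0.14. Plasma cell markers had 0 of 9 changed by limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; camera adjusted p = 0.952, directed down against a median of 0.12). Adipocyte markers had 1 of 15 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.915), with Plin4, a lipid droplet gene, at -1.15 (SE 0.156). Smooth and skeletal muscle had 1 of 12 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.361). Mesothelial markers had 1 of 7 lower and 0 higher (0 adjusted over the list alone), although the list median was 0.37 and its mean 0.25 (camera adjusted p = 0.653, directed up). The lower one, Krt14, was at -0.30, and its call was lost in 9 of 17 other settings, with adjusted p-values of up to 0.538. Gut and liver markers had 1 of 11 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.361), with Lgals4, a galectin gene, 2.84-fold higher. Only 3 erythroid genes were measured, too few for the set test; 1 of them, Slc4a1, was lower by limma (-0.64, SE 0.118; 2 lower adjusted over the list alone).

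**Figure D3:**
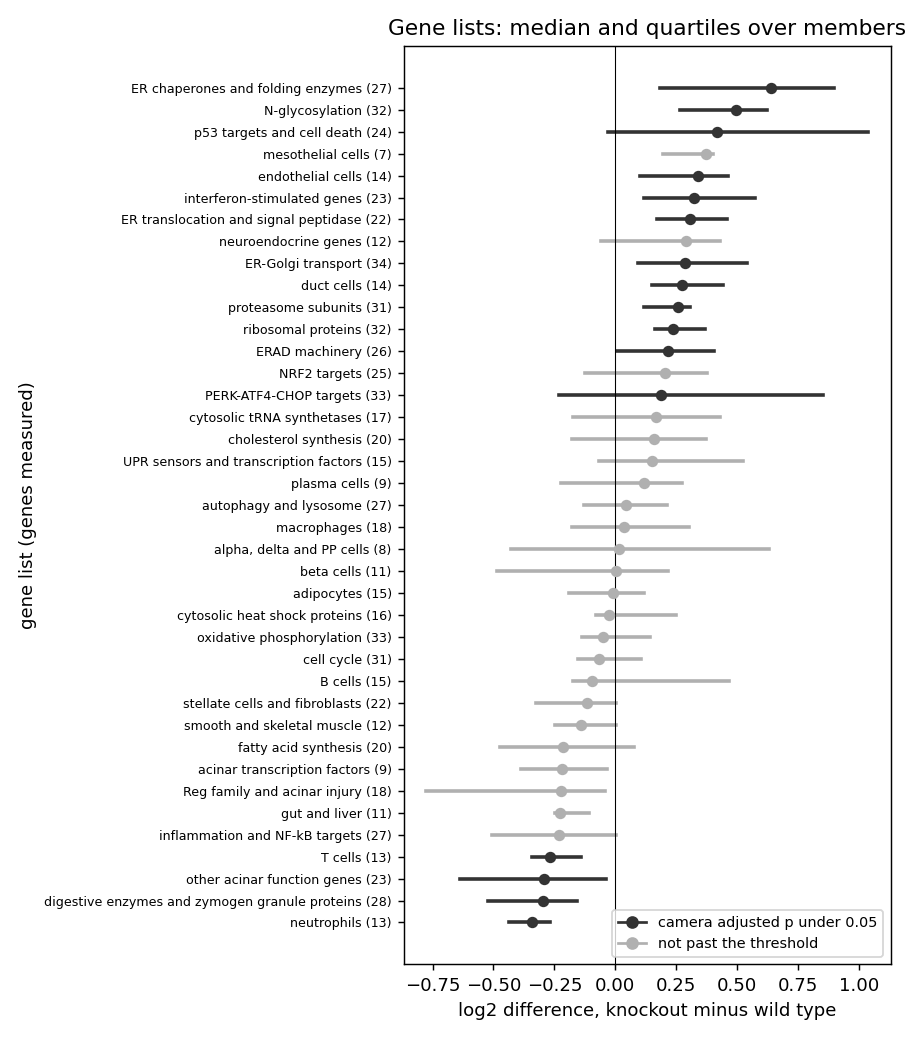
Median (points) and quartiles (bars) of the log2 difference, knockout minus wild type, over the members of each of the 39 gene lists tested, with the number of genes measured in parentheses; dark lists passed a camera adjusted p of 0.05 with the preset correlation. The medians ran from 0.64 for ER chaperones and folding enzymes to -0.34 for neutrophils, and with an estimated correlation no list passed.

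In all, 16 of 39 lists passed camera with a preset correlation of 0.01, 12 higher and 4 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.509 and 2 lists had an unadjusted p under 0.05. With fry 22 lists passed, 15 of them among those called by camera. With the Xist covariate camera called 9 further lists: lower for cell cycle, stellate cells and fibroblasts, macrophages, plasma cells, the Reg family and acinar injury, inflammation and NF-kB targets and acinar transcription factors, and higher for cytosolic tRNA synthetases and neuroendocrine genes. The Xist level correlated with genotype (Pearson r of 0.891), and the covariate moved the differences themselves. The list median went from 0.04 to -1.67 for macrophages and from 0.29 to 0.84 for neuroendocrine genes. These 9 calls therefore rest on differences that the arrays cannot separate well from the Xist level. Other divisions of the same 8 arrays into 4 and 4 called up to 26 lists, so the number of lists called does not exceed what such divisions give.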

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

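The tests of array background, of p53 targets and of liver RNA were chosen after their results, or most of the values they rest on, had been seen; the counts over other divisions of the arrays were planned before they were run.

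All 35 divisions of the 8 arrays into 4 and 4 were fitted. For genes changed (5406), genes higher (3027), genes lower (2379) and genes changed at least 2-fold (434), 1 of the 35 splits, the real one, gave a count as large. The highest of the other splits was 0 for each. A rank of 1 of 35 is the most that these splits can show. Each other split mixes both genotypes, so the genotype difference widens the spread within its groups and lowers its count. The counts of 0 therefore do not measure what chance division gives without that difference, and chance is not excluded by them. For gene lists changed the real count was 16, 12 of the 35 splits gave as many, and the highest other split gave 26, so chance division cannot be excluded for the number of lists called by camera. The split with 26 set wild type replicates 1, 3 and 4 with knockout replicate 1 against the rest, which points to a structure among the samples other than genotype.

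Most outliers were single values. Within groups of 4, the gap to the nearest other value, as a share of the group's range, passed the critical value of Dixon's test in 16 of 360 groups tested, where chance gives about 18. For genes, the ratio was 0.862 for Sel1l in knockout replicate 4 (11.45, others from 11.66 to 11.7), 0.838 for Gal in wild type replicate 3, 0.834 for Cdhr2 in wild type replicate 2, 0.95 for Ero1a in wild type replicate 3, 0.856 for Eprs in wild type replicate 1, 0.84 for Sec61g in wild type replicate 4 and 0.882 for Psma1 in knockout replicate 4. It was 0.908 for Cldn7 in wild type replicate 3, 0.865 for Col5a1 in knockout replicate 1, 0.845 for Vpreb3 in knockout replicate 2 (7.15, others at most 5.94), 0.858 for Alas2 in wild type replicate 4, and for Slc4a1 0.944 in wild type replicate 2 and 0.875 in knockout replicate 1. For list means, wild type replicate 1 lay below the other wild type arrays for ER chaperones and folding enzymes (0.837; 9.93 against 10.06 to 10.09), ER translocation and signal peptidase (0.848; 9.92 against 10.04 to 10.07) and N-glycosylation (0.961; 8.36 against 8.58 to 8.59). With the preset correlation these 3 lists were called higher also without that array; with an estimated correlation none of the 3 was called (adjusted p = 0.509 for each).

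Features outside the gene-level test also differed. In a fit of every feature, 1157 features with no gene listed were higher in the knockout arrays and 922 lower, and of features shared by several genes 239 were higher and 140 lower.

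Dim genes were lower more often than higher: among genes below the median level 1367 were lower and 405 higher, against 1012 and 2622 above it; a lower array background in the knockout arrays could account for part of this. The 1192 receptor genes that pancreas is not known to express had a median difference of -0.18 (quartiles -0.28 and -0.09), 90.3% of them lay lower and 172 were called lower, and after cyclic loess their median was -0.03 and 610 dim genes were called lower and 454 higher. For 13 dim genes the fall exceeded, by more than 2 SE, that of every receptor gene on the deposited values, where the largest was 0.94. The same 13 did so after cyclic loess, where the largest was 0.82. Of these, Cdhr2 fell by 2.19 (SE 0.113), and by 2.17 after cyclic loess. The 13 genes were picked by exceeding that bound. The receptor genes were also dimmer, at a median level of 2.62 against 4.79 or more for the 13 genes in wild type. A lower background is therefore not excluded for the 13 genes as a set. Unnamed features listed before the first named one went both ways. The first 66, a run defined from the data as falling, had a median of -0.55 and reached -1.21. Cdhr2 fell beyond that value by more than 2 SE, whereas Klhdc8a (-1.30, SE 0.152), also among the 13 genes, did not. The other 6550 unnamed features had a median of 0.21, with 818 called higher and 237 lower. A lower background stays open for the falls of dim genes, at least as part of the cause, and loss of Sel1L and Cre activity stay open for all.

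Of 24 p53 targets and cell death genes, 11 were called higher and 3 lower, with a list median of 0.42 (camera adjusted p = 0.000279, adjusted p = 0.509 with an estimated correlation). The 22 members not on the PERK-ATF4-CHOP list had a median of 0.42 as well, so the shared members alone do not make up the rise. Only 2 members are shared, so leaving them out could hardly have moved the median. Whether ATF4 or CHOP acts on the other members was not tested. Cre recombinase in the knockout group cannot be told apart from loss of Sel1L, since no Cre-carrying mouse with intact Sel1l is in the design; the rise of Esr1 by 2.15, which may reflect the Cre fusion if its feature reads the transgene, shows only that the groups differ in it. Both explanations stay open.

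Genes known from liver, Fetub, Cps1, Ahsg and Serpina6, were among the largest rises. Vtn, which is on the list of liver transcripts used here, was among the largest falls (-3.37). RNA from liver in the knockout samples is argued against: 26 measured transcripts abundant in liver, from a list written after some of their values, such as those of Alb and Vtn, had been seen, had a median difference of -0.27 (quartiles -0.41 and -0.11), with 3 called higher and 6 lower; 5 of them are on another list and 11 lay above the median level of all genes in wild type pancreas. Alb lay at 6.15 in the wild type and 5.38 in the knockout arrays, and Apoa1 at 4.81 and 4.58. Loss of Sel1L and Cre activity both stay open for these rises, and no test here decides between them.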

How the results depend on the processing

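Cyclic loess was chosen after seeing the data. Of the 5406 genes called on the deposited values, 0 changed sign under quantile normalization, centring, cyclic loess or leaving out an array, 9 with the mean of all features of a gene and 183 with the Xist covariate. Centring moved the median difference of all genes from -0.037 to -0.144, so changes under it are relative to that shift. Higher genes numbered 1815 after quantile normalization, 1868 after centring (with 4014 lower) and 1987 after cyclic loess; 1163 genes were lower among genes above the median level, where fewer genes were tested, and features, in place of genes changed at least 2-fold, numbered 960 with every feature tested by itself, where more were tested. With the Xist covariate 181 genes were called, 141 higher and 40 lower, with 169 genes changed at least 2-fold and 98 of the 127 named genes that had passed the threshold no longer past it; Sel1l was at -0.90 (adjusted p = 0.0587, range over alternatives 4.31e-06 to 0.0587), and Rsad2 (-0.075), Cd8a (0.21) and the interferon list (-0.19) turned direction. The same covariate newly called 9 lists, among them stellate cells and fibroblasts (-1.05, adjusted p = 2.16e-08), cell cycle (-0.62, 9.23e-06), the Reg family (-1.07, 6.87e-05) and macrophages (-1.67, 0.00068). Gene lists called numbered 10 after quantile normalization and 0 with camera and an estimated correlation, where 2 had an unadjusted p under 0.05. The Xist level correlated with genotype at a Pearson r of 0.891 over all arrays. The Xist covariate therefore widens the error of the genotype difference and can move the difference itself. Calls lost with it therefore do not show by themselves that these changes depend on sex. On every array Xist lay between 10.7 and 11.25, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 1.96 and 2.83. These values argue against a difference in sex between the groups. The cause of the other shifts was not tested. Leaving out each array in turn gave 3721 to 5227 genes changed, 2204 to 2856 higher, 1517 to 2371 lower, 408 to 470 genes changed at least 2-fold, 14 to 19 lists and a Sel1l difference of -0.78 to -0.70. With the replicate block 4678 genes were called (2680 higher, 1998 lower) and 15 lists, the PERK-ATF4-CHOP list being lost (adjusted p = 0.0563). Deviations of same-numbered arrays correlated at 0.222, 0.153, -0.273 and -0.0195 across genes, and not every array correlated best with its own number. A regular pairing by number was therefore not seen, but this check cannot exclude one. Dim signals near array background limit what the arrays resolve, as the receptor genes show at a median level of 2.62.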

Other observations

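Within the Reg family, secreted proteins of injured acinar cells, Reg3a and Reg2, singled out after their values were seen, varied widely inside each group, while Reg1 did not (13.4 to 13.66 in wild type and 12.83 to 13.21 in knockout arrays). Reg3a lay at 6.53 in wild type replicate 2 against 11.07 to 12.66 in the other wild type arrays, and at 5.84 in knockout replicate 3 against 7.61 to 9.37 in the other knockout arrays. Reg2 was lowest of its group in the same arrays, at 11.17 and 9.61, and so were Reg3b (8.412 and 8.415) and Reg3d (12.43 and 11.32). Reg3b also varied widely in wild type, up to 13.1. Reg3g was lowest in wild type replicate 2 (8.28), but among the knockout arrays in replicate 4 (9.41) and not in replicate 3 (9.57). These differences lie within groups, and no explanation was tested.

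Further members of the p53 list, named after their values were seen, were called in both directions by limma. Cdkn1a, the gene of the cell cycle inhibitor p21, rose by 2.26 (SE 0.239), Sesn2 by 1.76 (SE 0.18) and Mdm2, the ligase gene that p53 itself induces, by 0.47 (SE 0.104). Plk2 fell by 1.45 (SE 0.245), Gadd45b by 1.05 (SE 0.133) and Pmaip1 by 0.41 (SE 0.128).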
